A study of Homo sapiens with 30 samples.

How the data were processed

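RNA was sequenced from 30 samples of the human colorectal carcinoma line HCT116, wild-type for p53 or p53-null, in 2 experiments of 18 and 12 samples, each with its own table. Per the labels' protocols, total RNA was extracted on silica columns with a DNase step and poly(A) RNA was selected on magnetic beads. Libraries were made with a kit that the labels do not describe as stranded, and were sequenced on a NextSeq500. Per the submitters' processing notes, CASAVA, FastQC, TopHat2 and Bowtie were used with the human build hg19. The versions, the read counter and the annotation are not given in the sources used here.

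The authors deposited log2 CPM, the base-2 logarithm of the reads of a gene scaled to a total of 1000000 reads assigned to genes per library, as 1 value per gene and library. No pseudocount had been added: the antilogs of each library summed to 1000000, a gene without a read was entered as not available, and every value was a whole multiple of 1 read within a tolerance of 0.01 (100% of values). Reads per library were recovered from these steps, and each missing value was set to 0.5 reads before the logarithm. The first table had 57396 gene identifiers and the second 57773 distinct ones, of which 61 were listed more than once with identical values and kept once. Gene symbols came from a GENCODE annotation of a later genome build than the authors used, so no coordinates are given. They matched 95.2% of the 28441 identifiers with a read in the first table and 96.3% of the 25753 in the second. Genes that overlap others or have near-identical copies, such as IDI1, the keratins KRT6A, KRT6B and KRT6C and duplicated histone genes, are uncertain, because the counting of shared reads and the use of strand are not given in the sources used here.

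Libraries held 3611729 to 7034653 assigned reads. A gene seen in 3 reads, the floor used for a group without reads, stood at 0.426 to 0.831 CPM, depending on the library. A fold change against a group without a read is given as a lower bound from this floor, taken per library, and groups with 1 to 3 reads are described by their level only. Such floors cover counting error only, since reads copied by PCR are not independent molecules.

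Samples were grouped by genotype, growth environment and treatment as their titles state, 10 groups of 3. Nothing in the labels says that replicates came from separate cultures or mice, so p-values measure the spread between these samples, which may be technical. All 30 pairs of replicates within a group differed by more than sampling noise, with a chi-square per gene of 1.62 to 19.3 over genes with at least 20 reads in the pair, so each library was counted once. The 2 tables were never combined in a test.

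Each of 13 comparisons, of which 10 compared 2 groups and 3 compared differences, was fitted to the log2 CPM with limma's lmFit and eBayes with an intensity trend, using only the libraries of the groups compared and the genes at 1 CPM or more in at least 3 of them. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The design had assumed log2 CPM, so no count test was planned, and limma with voom weights on the recovered reads was added after the data were seen. So was a comparison of the genotypes under simvastatin, given for the sterol synthesis list only. For 36 gene lists written from textbook knowledge, limma's camera was run with a preset inter-gene correlation of 0.01 on lists with at least 5 tested members, with adjustment over the lists of one comparison. Camera with an estimated correlation was run beside it, and fry, which asks whether a list's genes move one way on balance and compares no list with other genes. The 13 comparisons, their tests, the lists, the alternatives not said to be added and the rule for naming genes were chosen before the data were examined. The named genes were the 8 called genes with the largest rise and the 8 with the largest fall in each comparison (a mean of at least 8 CPM in the higher group, no overlap of replicates for 2 groups, no clone names), up to 4 called members of each list with the largest change, and 26 genes named whatever their result. Results of some genes and of a gene list are not reported here. Agreement between comparisons that share no library was described across genes with Pearson's r, Spearman's rho and shared calls.

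The statistics were tested on simulated data made from the real means and depths. Genes were drawn independently around the means of a single group, with no deviations shared by the genes of a library. The shares below therefore need not hold for the real libraries, whose counts moved when single libraries were left out. In the 14384 genes of the monolayer genotype comparison, 24.6% of 1.5-fold, 69.2% of 2-fold and 84.6% of 4-fold changes were recovered, and 4.13% of calls were false. For wild-type simvastatin spheroids (14244 genes) these shares were 41.5%, 83.3% and 95.3%, with 6.54% false. For tumour genotypes (18094 genes) they were 0%, 13.8% and 54.7%, with 4.35% false, and for the genotype difference between spheroids and monolayers (14958 genes) 4.69%, 45.5% and 79.0%, with 3.53% false.

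Alternatives were no filter, a stricter filter of a mean of 8 CPM, log2(CPM + 1), quantile normalization, a shift of each library to a common median, no trend with a robust prior, all groups of a table in the fit, the replicate number as a block, each library left out in turn, and, added after the data were seen, voom and nuclear protein-coding genes only. Fits without a library kept the gene set of all libraries. No column of either table was left unmapped. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.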

Results

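Gene expression was measured by RNA sequencing in 30 libraries from HCT116, a human colorectal carcinoma line with wild-type p53, and from its p53-null derivative. The libraries formed 10 groups of 3 replicates in 2 experiments. The first experiment held 18 libraries of cells of both genotypes grown as a monolayer, as spheroids started from 10000 cells each, or as tumours in mice. The second held 12 libraries of spheroids of both genotypes that received 10 µM simvastatin, an inhibitor of the mevalonate pathway, or the solvent DMSO for 72 h. The design asked how loss of p53 alters expression in 3 growth environments and under a statin. Genotype was compared between the parental line and this derivative, so loss of p53 was not separated from other differences between the lines. Tumour cells also carried luciferase and a control short hairpin RNA and the mice received doxycycline in their food, so the tumour environment was not separated from these. Each library held 3611729 to 7034653 reads assigned to genes, and 1 read was worth 0.142 to 0.277 counts per 1000000 assigned reads (CPM). Tumour libraries were the shallowest, at 3611729 to 4306023 reads, yet had reads in 22310 to 23595 genes, against 18892 to 19487 genes in the cultured libraries of the first experiment. The mitochondrial genome took 8.80 to 16.0% of reads in tumours and 1.44 to 5.83% in the cultured libraries of that experiment. Levels are given as mean ± SD of 3 libraries, fold changes on the log2 scale with the standard error (SE), and adjusted p-values are those of limma. For spheroids and tumours against monolayers, medians of gene lists are relative to the median of all genes, while single-gene values are on the deposited scale. Where a single count of a list's members is given, the count adjusted over the list alone was the same.

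CDKN1A (ENSG00000124762), which encodes the cell cycle inhibitor p21 and is a direct target of p53, was at 225 ± 11.1 CPM in wild-type and 37.9 ± 4.95 CPM in p53-null monolayers. In spheroids the corresponding levels were 237 ± 10.4 CPM and 176 ± 3.92 CPM, and in tumours 128 ± 12.1 CPM and 141 ± 32.4 CPM.

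**Figure D1:**
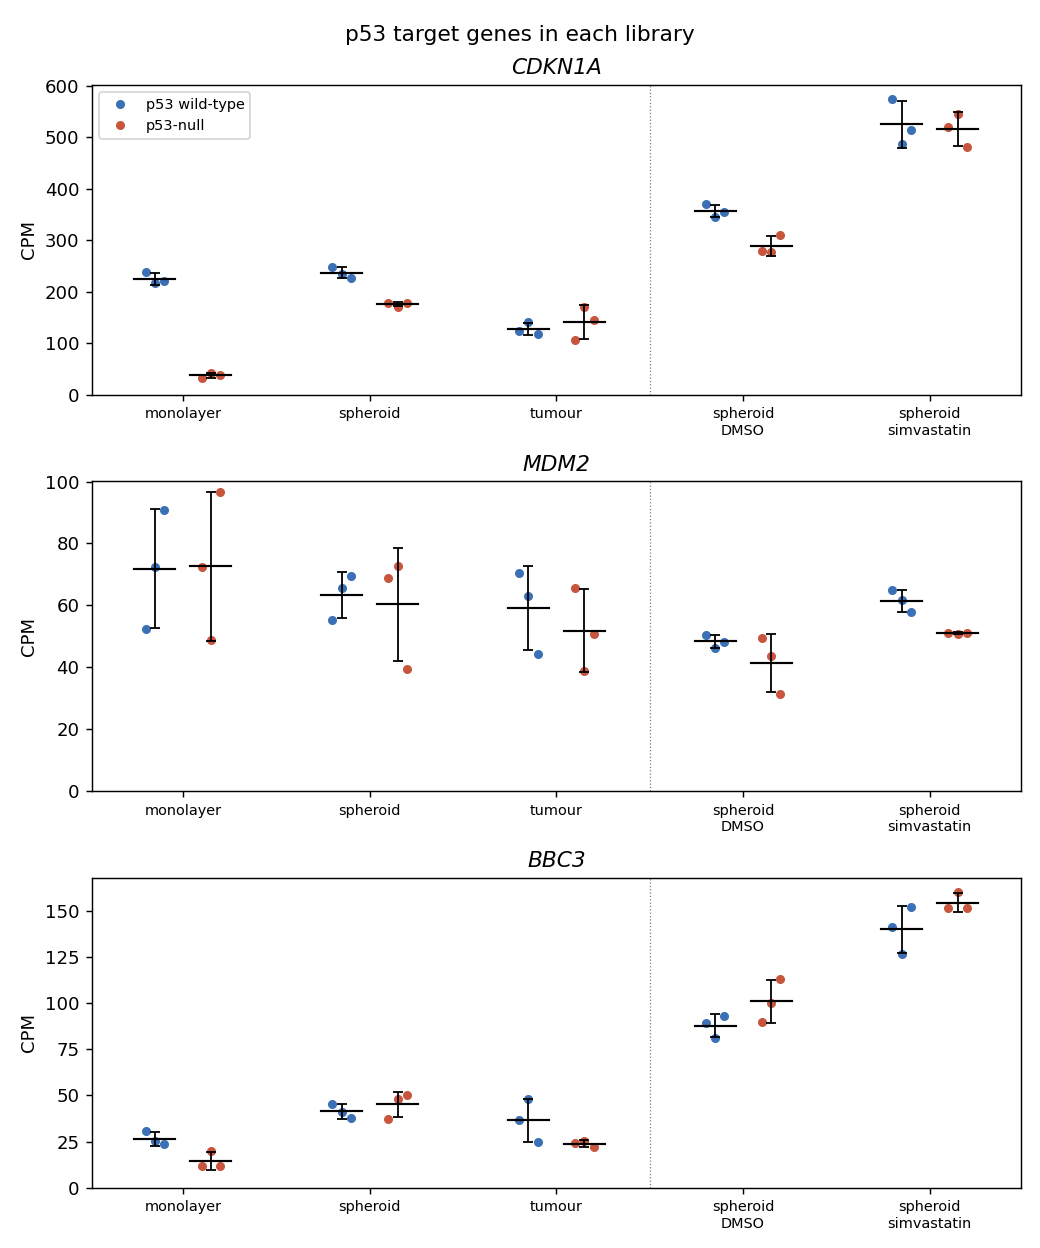
CPM of CDKN1A, MDM2 and BBC3 (vertical axes) in each library (dots) of the 10 groups (horizontal axes), with the mean of 3 libraries as a bar and the SD as an error bar. CDKN1A is 225 against 37.9 CPM in monolayers and 128 against 141 CPM in tumours.

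In monolayers, loss of p53 went with lower expression of p53 target genes. CDKN1A was lower in p53-null cells (log2 fold change -2.58, SE 0.11, adjusted p = 8.33e-06). So were GDF15, a stress-induced cytokine of the TGF-beta family (log2 fold change -1.64, SE 0.12, adjusted p = 0.000120), the death receptor gene FAS (log2 fold change -1.10, SE 0.15, adjusted p = 0.00301) and the antiproliferative gene BTG2 (log2 fold change -1.09, SE 0.12, adjusted p = 0.00129). Of the 36 tested p53 targets, 12 changed, 1 upward and 11 downward, and 14 changed when adjusted over the list alone, 1 upward and 13 downward. Their median log2 fold change was -0.33 (camera adjusted p = 5.55e-08, and adjusted p = 0.0643 with an estimated correlation). MDM2, the ubiquitin ligase gene that p53 also induces, did not pass the test (log2 fold change -0.0046, SE 0.26, adjusted p = 0.994), with the opposite sign without p53-null replicate 2 (0.26), wild-type replicate 2 (0.018) or wild-type replicate 3 (0.18).

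Larger differences lay outside the p53 targets. PRKAA2, a catalytic subunit of AMP-activated kinase (-4.34, SE 0.35), SYK, a tyrosine kinase (-4.23, SE 0.18), RGS2, a regulator of G protein signalling (-4.96, SE 0.22), and the inflammatory caspase gene CASP4 (-7.04, SE 0.56) were lower in p53-null monolayers. NRIP1, a nuclear receptor corepressor gene, had no read in the 3 p53-null libraries and was at least 59.2-fold lower (floor of 3 reads per library). The epithelial transcription factor gene EHF was at 109 ± 17.4 CPM in wild-type cells and 0.164 ± 0.161 CPM, 3 reads in all, in p53-null cells. Higher in p53-null cells were the Notch ligand gene DNER (2.79, SE 0.21), WNT16 (2.37, SE 0.11), the cell adhesion gene NECTIN3 (2.08, SE 0.14) and ANXA10 (1.98, SE 0.15). Of 19 MYC and ribosome biogenesis genes 3 were lower, NOLC1 (-1.29, SE 0.09) and GNL3 (-1.001, SE 0.09) among them, and the list did not pass camera (median 0.05; camera adjusted p = 0.486, and adjusted p = 0.656 with an estimated correlation). Of the 8 tested interferon response genes 3 fell, and the list's median was -0.44 (camera adjusted p = 0.00607, and adjusted p = 0.267 with an estimated correlation).

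Sterol synthesis genes differed little between monolayers. Of 20 tested members of the mevalonate and sterol synthesis list 2 fell, and the list's median log2 fold change was 0.13 (camera adjusted p = 0.400). HMGCS1, the HMG-CoA synthase gene (log2 fold change 0.16, SE 0.17, adjusted p = 0.614) and INSIG1, which restrains SREBP processing (log2 fold change 0.16, SE 0.08, adjusted p = 0.278) did not pass the test. HMGCS1 was at -0.0087 without p53-null replicate 3. In all, 947 of 14447 genes differed between the genotypes, 386 higher and 561 lower in p53-null cells, of which 138 and 265 by at least 2-fold. That count rested on single libraries: it was 416 without p53-null replicate 1, 1913 without p53-null replicate 2, and 498, 295 and 492 without wild-type replicate 1, 2 or 3.

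In spheroids, p53-null cells had higher expression of sterol synthesis genes than wild-type cells. HMGCS1 was 100.5 ± 12.9 CPM in wild-type and 216 ± 43.7 CPM in p53-null spheroids (log2 fold change 1.09, SE 0.14, adjusted p = 0.000157). ACAT2 (1.39, SE 0.13) and the methylsterol oxidase gene MSMO1 (1.26, SE 0.10) rose as well. Of 20 members, 15 were higher and 1 lower (16 and 1 when adjusted over the list alone), with a median of 0.70 (camera adjusted p = 1.27e-14, and adjusted p = 0.0370 with an estimated correlation). The lower member was squalene epoxidase, SQLE (log2 fold change -0.78, SE 0.10, adjusted p = 9.72e-05). INSIG1 (1.12, SE 0.10) and the acetyl-CoA synthetase gene ACSS2 (1.38, SE 0.10) were among the 8 of 12 genes of sterol uptake and SREBP regulation that rose (9 over the list alone) (median 0.58; camera adjusted p = 8.97e-11, and adjusted p = 0.0546 with an estimated correlation). Fatty acid synthase, FASN, was also higher (0.68, SE 0.09).

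**Figure D2:**
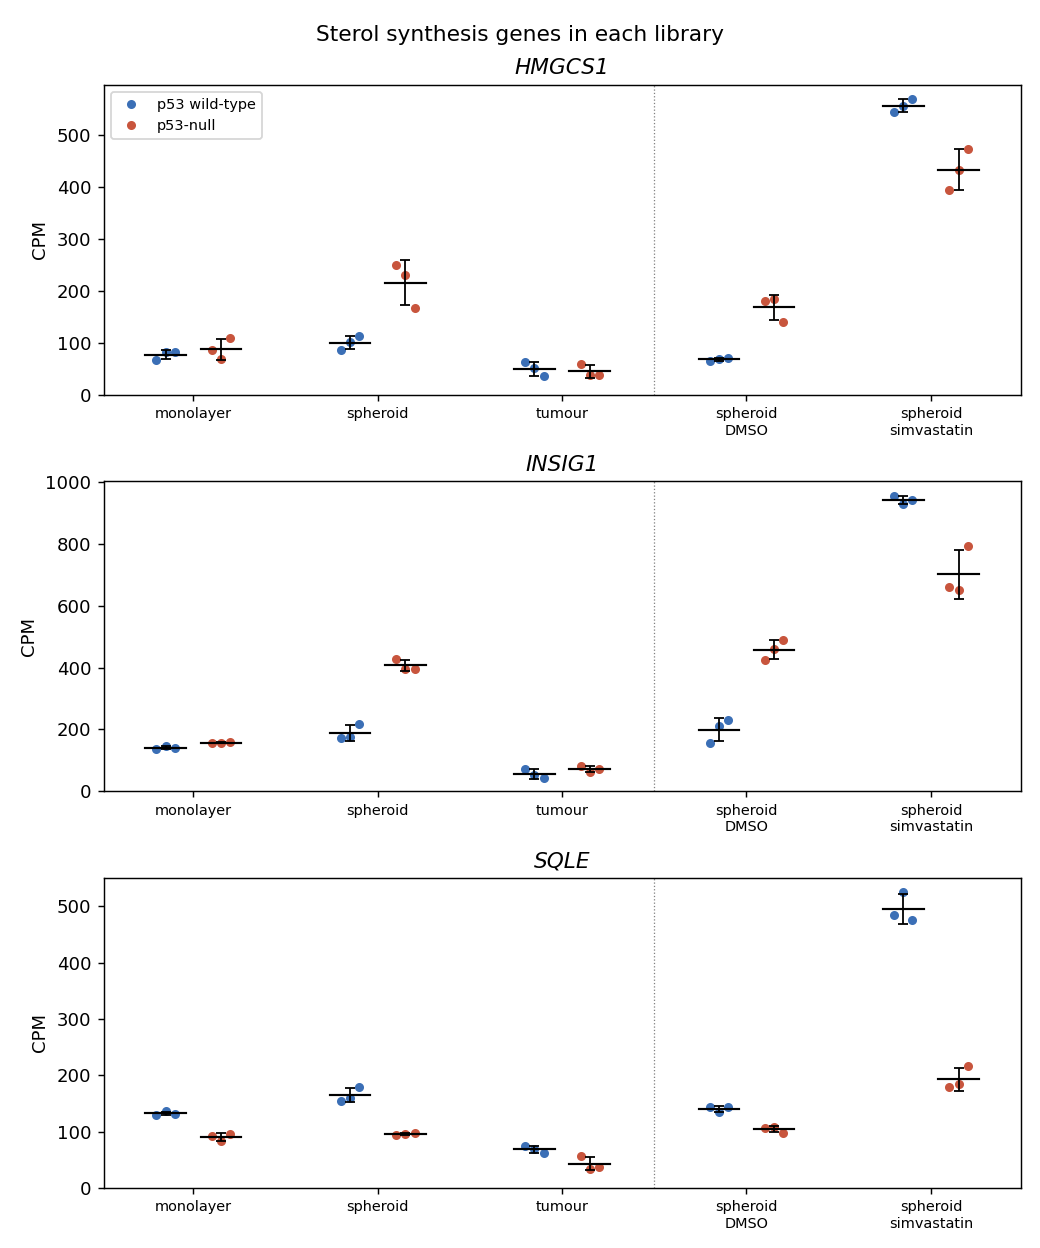
CPM of HMGCS1, INSIG1 and SQLE (vertical axes) in each library (dots) of the 10 groups (horizontal axes), with the mean of 3 libraries as a bar and the SD as an error bar. HMGCS1 is 100.5 CPM in wild-type and 216 CPM in p53-null spheroids, and 557 and 434 CPM in simvastatin-treated spheroids.

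Of 36 p53 targets 5 were higher and 10 lower in p53-null spheroids (5 and 15 over the list alone; median -0.27). The list did not pass camera (adjusted p = 0.0765) but was called lower by fry (adjusted p = 0.00888). FAS (-1.39, SE 0.19), the DNA repair gene DDB2 (-1.11, SE 0.13) and GDF15 (-1.08, SE 0.12) were lower, and the polo-like kinase gene PLK2 was higher (1.75, SE 0.12). Of 8 tested histone genes 7 were higher (median 1.04; camera adjusted p = 1.88e-14, and adjusted p = 0.0546 with an estimated correlation), led by H2BC21 (3.07, SE 0.12). Interferon response genes were lower in 11 of 13 (12 over the list alone; median -0.72; camera adjusted p = 2.64e-11, and adjusted p = 0.0546 with an estimated correlation), among them XAF1 (-1.79, SE 0.25), IFI44 (-1.78, SE 0.12) and OAS1, which senses double-stranded RNA (-1.33, SE 0.22). Genes of the integrated stress response rose in 9 of 18 and fell in 2 (9 and 3 over the list alone; median 0.33; camera adjusted p = 0.000320, and adjusted p = 0.0768 with an estimated correlation), with CHAC1 (1.72, SE 0.17) and asparagine synthetase, ASNS (0.53, SE 0.09), among the higher ones.

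Other large differences in spheroids included the collagen gene COL17A1 (3.07, SE 0.17) and the TGF-beta pseudoreceptor gene BAMBI (3.42, SE 0.17), both higher in p53-null cells. SPARC, a matrix protein gene, was higher in p53-null spheroids (3.08, SE 0.27) and lower in p53-null monolayers (-2.80, SE 0.28). NRIP1, the insulin-like growth factor-binding gene IGFBP3 and PROM1, which encodes a stem cell surface marker, had no read in p53-null spheroids and were at least 70.8-fold, 68.9-fold and 59.6-fold lower. The gap junction gene GJA1 was at 39.6 ± 5.03 CPM in p53-null and 0.104 ± 0.0901 CPM, 2 reads in all, in wild-type spheroids. Tissue factor, F3, was lower (-2.01, SE 0.10). Of 14321 genes, 1664 differed, 517 higher and 1147 lower, of which 155 and 377 by at least 2-fold, and a shift of each library to a common median gave 862 and 843. Single libraries moved the count to 2865 (without p53-null replicate 3), 1012 (without wild-type replicate 1) and 933 (without wild-type replicate 2).

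The DMSO-treated spheroids of the second experiment gave the genotype comparison again, in libraries not shared with the first. HMGCS1 was 68.7 ± 2.89 CPM in wild-type and 168 ± 24.98 CPM in p53-null spheroids (log2 fold change 1.28, SE 0.11, adjusted p = 1.33e-07). INSIG1 rose by 1.21 (SE 0.12), while SQLE was lower (-0.43, SE 0.09). The sterol synthesis list was higher in 13 and lower in 1 of 20 (17 and 1 over the list alone; median 0.68; camera adjusted p = 6.48e-14, and adjusted p = 0.0686 with an estimated correlation). The p53 targets were higher in 4 and lower in 13 of 36 (5 and 15 over the list alone; median -0.23; camera adjusted p = 0.0370, and adjusted p = 0.473 with an estimated correlation), with an adjusted p of 0.0501 with the replicate number as a block and 0.00536 to 0.473 over the alternatives. Lower in p53-null spheroids were FAS (-1.23, SE 0.20), DDB2 (-0.94, SE 0.12) and GDF15 (-0.87, SE 0.11). Conversely, PLK2 (1.60, SE 0.11), the hypoxia-induced carbonic anhydrase gene CA9 (2.53, SE 0.13), COL17A1 (3.63, SE 0.23), BAMBI (3.52, SE 0.18) and the growth factor-binding gene FGFBP1 (3.44, SE 0.17) were higher. VEGFA, also on the hypoxia list, did not go with CA9. It was at 257 to 283 CPM in p53-null and 308 to 391 CPM in wild-type DMSO spheroids. In spheroids of the first experiment it was at 235 to 253 CPM and 312 to 326 CPM. Transcripts of the mitochondrial genome rose in 12 of 13 (13 over the list alone; median 0.54; camera adjusted p = 1.05e-12, and adjusted p = 0.221 with an estimated correlation). Histone genes rose in 6 of 9 (median 0.83; camera adjusted p = 2.66e-06, and adjusted p = 0.167 with an estimated correlation). Of 14267 genes, 2262 differed, 774 higher and 1488 lower, of which 172 and 408 by at least 2-fold, and a median shift gave 1198 and 1155. The count was 1479 without p53-null DMSO replicate 2, and 1480 and 1278 without wild-type DMSO replicate 1 or 3.

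Across the 13748 genes tested in both spheroid experiments, the genotype effects correlated with Pearson's r of 0.787 and Spearman's rho of 0.611, and 72.9% had the same sign, genes not being independent replicates. Both experiments called 369 genes higher and 756 lower in p53-null spheroids, where lists drawn independently would share 27.9 and 119.

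Among tumours, KRT14 (4.23, SE 0.44) and KRT5 (4.01, SE 0.22), keratins of basal epithelium, were higher in p53-null than in wild-type tumours. So was KRT6A (5.68, SE 0.40), whose reads cannot be separated with certainty from its near-identical copies KRT6B and KRT6C. GJA1 was also higher (5.66, SE 0.63). EHF (-7.03, SE 0.30), NRIP1 (-5.17, SE 0.39), PROM1 (-4.26, SE 0.42) and the adhesion receptor gene ADGRF1 (-5.00, SE 0.50) were lower. CA9 was higher (log2 fold change 2.26, SE 0.32, adjusted p = 0.000661). The levels of VEGFA overlapped, at 130 to 164 CPM in p53-null and 72.8 to 156 CPM in wild-type tumours. Of 36 p53 targets 3 changed, all upward (4 upward and 3 downward over the list alone), and the list did not pass the test (median -0.12; camera adjusted p = 0.900). SERPINB5, the maspin gene, was among them (1.22, SE 0.20).

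Sterol synthesis genes taken singly did not pass the test in tumours. None of 20 was called by limma, 5 were higher and 1 lower at an unadjusted p under 0.05, and 2 were higher and 1 lower when adjusted over the list alone. The list lay above other genes only in camera with the preset correlation (median 0.32; camera adjusted p = 0.00140, and adjusted p = 0.481 with an estimated correlation). Fry did not call it (adjusted p = 0.249). INSIG1 (log2 fold change 0.41, SE 0.22, adjusted p = 0.492), HMGCS1 (log2 fold change -0.16, SE 0.25, adjusted p = 0.877; 0.028 without wild-type tumour replicate 1) and CDKN1A (log2 fold change 0.12, SE 0.19, adjusted p = 0.888; -0.033 without p53-null tumour replicate 2) were not called. Interferon response genes were lower in 2 of 13 (4 over the list alone; median -0.36; camera adjusted p = 0.000295, and adjusted p = 0.481 with an estimated correlation), among them IFI44L (-2.86, SE 0.31). Of 18178 genes, 417 differed, 176 higher and 241 lower, of which 126 and 216 by at least 2-fold. The count was 230 without p53-null tumour replicate 2 and 199 without p53-null tumour replicate 3, and in simulated libraries the test recovered 13.8% of 2-fold and 54.7% of 4-fold changes for this comparison.

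The genotype effect itself was compared between environments. Here a higher effect means a signed log2 fold change that is less negative or more positive, not a stronger effect. For CDKN1A it was 2.15 higher in spheroids (SE 0.14, adjusted p = 1.93e-06) and 2.70 higher in tumours (SE 0.23, adjusted p = 2.48e-05) than in monolayers. The drop of CDKN1A in p53-null monolayers was thus smaller in spheroids and was not seen in tumours. In spheroids against monolayers the genotype effect was also higher for MSMO1 (1.201, SE 0.14), ACAT2 (1.05, SE 0.16), ACSS2 (1.64, SE 0.15), SPARC (5.88, SE 0.42), H2BC21 (2.42, SE 0.35) and ASNS (0.84, SE 0.11), and lower for F3 (-1.97, SE 0.14). INSIG1 passed as well (log2 fold change 0.96, SE 0.13, adjusted p = 0.00195), though not when all groups of the first experiment shared the fit (adjusted p = 0.0529). HMGCS1 did not pass (log2 fold change 0.93, SE 0.24, adjusted p = 0.111). It did after quantile normalization (0.97, adjusted p = 0.0385) or a median shift (1.03, adjusted p = 0.0324), and without p53-null monolayer replicate 3 (1.10, adjusted p = 0.0354) or p53-null spheroid replicate 3 (1.11, adjusted p = 0.0330). Of 20 sterol synthesis genes 5 had a higher genotype effect in spheroids (11 over the list alone; median 0.56; camera adjusted p = 1.61e-16, and adjusted p = 0.000390 with an estimated correlation). Of 36 p53 targets 3 had one (6 higher and 1 lower over the list alone; median 0.18; camera adjusted p = 3.27e-06, and adjusted p = 0.00419 with an estimated correlation). In all, 131 of 15111 genes differed, 70 higher and 61 lower, and 109 and 50 after a median shift. The count was 87 without p53-null monolayer replicate 1, 200 without p53-null monolayer replicate 2, 65 without wild-type monolayer replicate 2, 78 without p53-null spheroid replicate 2, 66 without wild-type spheroid replicate 2 and 71 without wild-type spheroid replicate 3.

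Between tumours and monolayers, the genotype effect was higher for KRT6C (5.60, SE 0.73), with the same doubt over copies, and the peroxidasin gene PXDN (4.41, SE 0.47), and lower for the phosphatase gene PTP4A1 (-1.89, SE 0.26). HMGCS1 did not pass (log2 fold change -0.32, SE 0.32, adjusted p = 0.776). Of 36 p53 targets 2 had a higher genotype effect in tumours, CDKN1A and SERPINB5 (6 over the list alone; median 0.35; camera adjusted p = 1.78e-06, and adjusted p = 0.180 with an estimated correlation). For CDKN1A this means that the lower level of p53-null monolayers was not seen in tumours. In all, 75 of 18440 genes differed, 45 higher and 30 lower, and 48 and 49 after quantile normalization. The count lay between 30 and 44 without p53-null monolayer replicate 1 (34) or 3 (36), wild-type monolayer replicate 1 (32), 2 (44) or 3 (38), wild-type tumour replicate 1 (30) and p53-null tumour replicate 2 (38) or 3 (31), and was 129 without p53-null tumour replicate 1.

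Growth as spheroids changed 53.3% of the genes tested in wild-type cells. All 21 tested hypoxia response genes rose (median 3.05 relative to the median of all genes; camera adjusted p = 7.32e-28, and adjusted p = 0.0187 with an estimated correlation). They included the metastasis suppressor gene NDRG1 (5.37, SE 0.09), the lipase inhibitor gene ANGPTL4 (6.47, SE 0.13), the angiogenic factor VEGFA (2.99, SE 0.11) and CA9, which had no read in monolayers and was at least 24.7-fold higher in spheroids. Glycolysis genes rose in 16 of 20 and fell in 1 (median 0.73; camera adjusted p = 1.13e-10, and adjusted p = 0.0708 with an estimated correlation), among them the glucose transporter gene SLC2A1 (2.45, SE 0.09). All 13 interferon response genes rose, with IFI27 at 7.25, SE 0.20 and IFI44 at 6.47, SE 0.20 (median 5.91, or 5.00 with genes without a read in 1 group set to their bound; camera adjusted p = 2.57e-18, and adjusted p = 0.0214 with an estimated correlation). All 8 NF-kB and cytokine genes and all 11 immediate early genes rose too (adjusted p = 0.0214 and 0.0238 with an estimated correlation), with BIRC3, an inhibitor of apoptosis (3.87, SE 0.16), interleukin-8, CXCL8 (2.96, SE 0.22), and JUN (2.34, SE 0.12) among them.

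All 22 DNA replication genes fell in wild-type spheroids, such as CDC45 (-1.86, SE 0.12; list median -1.25 relative to all genes; camera adjusted p = 8.45e-15, and adjusted p = 0.0187 with an estimated correlation). All 24 mitosis genes fell as well, such as PLK1 (-1.64, SE 0.09; list median -1.29; camera adjusted p = 8.45e-15, and adjusted p = 0.0708 with an estimated correlation). Pyrimidine synthesis genes fell in 16 of 17 and rose in 1 (median -0.86; camera adjusted p = 1.71e-07, and adjusted p = 0.0214 with an estimated correlation). Thymidylate synthase, TYMS (-1.56, SE 0.09), and the genes of de novo synthesis CAD (-1.0, SE 0.10), DHODH (-0.87, SE 0.14) and UMPS (-0.89, SE 0.10) were lower. Of 20 genes of the TCA cycle 18 fell (19 over the list alone; median -0.47; camera adjusted p = 1.03e-05, and adjusted p = 0.0279 with an estimated correlation), including fumarate hydratase, FH (-1.36, SE 0.10). Respiratory chain genes of the nucleus fell in 21 of 23 (median -0.48; camera adjusted p = 4.43e-07, and adjusted p = 0.187 with an estimated correlation). Those of the mitochondrial genome rose in 10 of 13 (11 over the list alone; median 0.76; camera adjusted p = 9.84e-06, and adjusted p = 0.321 with an estimated correlation). Sterol synthesis genes rose in 4 and fell in 7 of 20 (median 0.01; camera adjusted p = 0.801), and CDKN1A was not called (log2 fold change 0.07, SE 0.08, adjusted p = 0.479). Of 14476 genes, 7714 changed, 2864 upward and 4850 downward, of which 996 and 1031 by at least 2-fold. The median over all genes lay at -0.14, so that a median shift gave 3685 upward and 3748 downward.

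In p53-null cells the move from monolayer to spheroid raised sterol synthesis genes and CDKN1A. CDKN1A rose from 37.9 ± 4.95 CPM to 176 ± 3.92 CPM (log2 fold change 2.22, SE 0.12, adjusted p = 3.74e-06), MSMO1 by 2.09 (SE 0.09), HMGCS1 by 1.30 (SE 0.19) and INSIG1 by 1.37 (SE 0.09). Of 20 sterol synthesis genes 9 rose and 1 fell (median 0.49 relative to all genes; camera adjusted p = 0.000220, and adjusted p = 0.0376 with an estimated correlation). The p53 targets rose in 14 of 36 and fell in 7 (median 0.38; camera adjusted p = 0.00271, and adjusted p = 0.0692 with an estimated correlation), with SESN2 (1.68, SE 0.14) and BBC3, the proapoptotic PUMA gene (1.67, SE 0.22), beside CDKN1A.

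In p53-null spheroids the hypoxia, interferon and cell cycle lists also changed. All 20 hypoxia genes (median 3.06 relative to all genes; adjusted p = 0.0234 with an estimated correlation), all 11 interferon genes (median 4.81, or 4.51 with bounds; adjusted p = 0.0234 with an estimated correlation), all 8 NF-kB genes and all 11 immediate early genes rose, with CA9 at 6.69, SE 0.52 and ANGPTL4 at 6.42, SE 0.16. All 22 DNA replication genes and all 24 mitosis genes fell (medians -1.23 and -1.23; adjusted p = 0.0376 and 0.0460 with an estimated correlation). So did 15 of 17 pyrimidine synthesis genes (1 higher and 16 lower over the list alone; median -0.91; adjusted p = 0.0312 with an estimated correlation). TYMS (-1.88, SE 0.12), CAD (-1.25, SE 0.16), DHODH (-1.16, SE 0.15) and UMPS (-0.85, SE 0.11) were lower. Histone genes rose in 7 of 9 (median 2.96; adjusted p = 0.0234 with an estimated correlation), led by H2BC21 (6.37, SE 0.26). The change differed between the genotypes for NF-kB and cytokine genes (median difference, p53-null minus wild-type, 0.55; camera adjusted p = 1.60e-05, and adjusted p = 0.00918 with an estimated correlation) and histone genes (0.69; camera adjusted p = 1.87e-09, and adjusted p = 0.00419 with an estimated correlation). RNA classes that lack a poly(A) tail also lay above protein-coding genes, by 0.94 in p53-null (6 genes, each higher) and 0.49 in wild-type spheroids (3 genes, 2 higher), and the histone changes were not separated from this. Of 14386 genes, 6744 changed, 2022 upward and 4722 downward, of which 884 and 1528 by at least 2-fold. The median over all genes lay at -0.25, and a median shift gave 3045 and 2893. Across 14040 genes tested in both genotypes, the spheroid effects correlated with r of 0.858 and rho of 0.834, and 1675 genes rose and 3760 fell in both, against 391.5 and 1596 for independent lists, with 21 called in opposite directions.

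**Figure D3:**
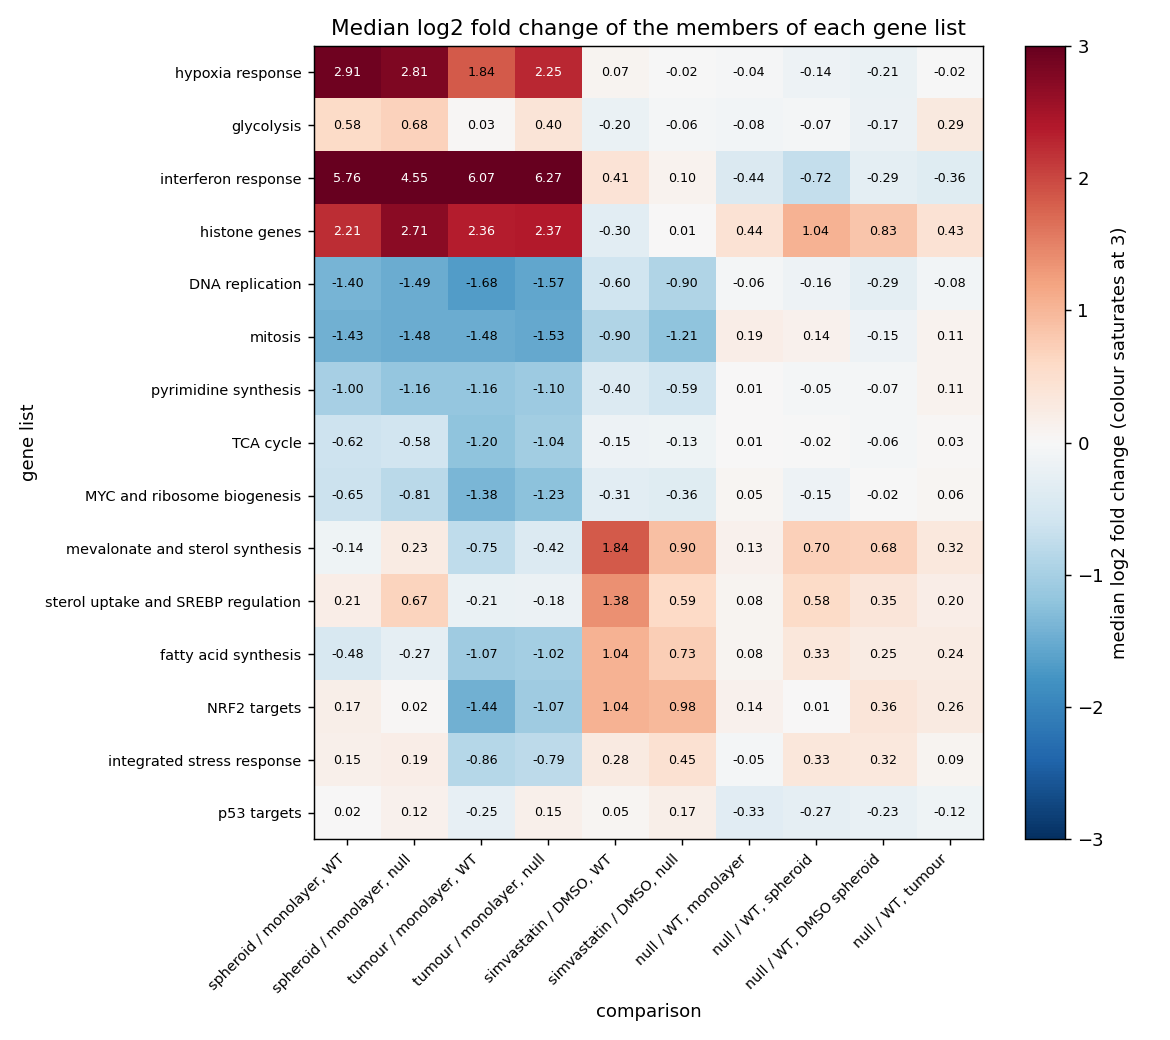
Median log2 fold change of the tested members of 15 gene lists (rows) in the 10 comparisons of 2 groups (columns), as a colour from -3 (lower) to 3 (higher) on the deposited scale. Interferon response genes have the highest medians in spheroids and tumours against monolayers, and the sterol synthesis list is at 1.84 and 0.90 with simvastatin.

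Tumour libraries differed from monolayer libraries in interferon, hypoxia, DNA replication and metabolic genes. In wild-type tumours, interferon response genes rose in all 13 (median 5.72 relative to all genes; camera adjusted p = 1.68e-07, and adjusted p = 0.0724 with an estimated correlation), with IFI27 at 8.22, SE 0.25 and XAF1, which had no read in monolayers, at least 135-fold higher. All 22 hypoxia genes rose (median 1.49; camera adjusted p = 4.09e-06, and adjusted p = 0.330 with an estimated correlation), among them NDRG1 (3.66, SE 0.13). DNA replication genes fell in 21 of 22 (22 over the list alone; median -2.03; camera adjusted p = 6.55e-12, and adjusted p = 0.0724 with an estimated correlation), with PCNA, the sliding clamp gene, at -2.26, SE 0.14. The proliferation marker gene MKI67 did not fall with them, at 449 to 482 CPM in wild-type tumours and 296 to 463 CPM in wild-type monolayers. Respiratory chain genes fell in all 23 (median -1.67; camera adjusted p = 1.68e-12, and adjusted p = 0.0724 with an estimated correlation). MYC and ribosome biogenesis genes fell in all 19 (median -1.74; camera adjusted p = 1.89e-11, and adjusted p = 0.0724 with an estimated correlation). Sterol synthesis genes fell in 14 of 20 (median -1.10; camera adjusted p = 1.22e-05, and adjusted p = 0.123 with an estimated correlation), HMGCS1 (log2 fold change -0.66, SE 0.20, adjusted p = 0.0119; adjusted p = 0.0512 without wild-type monolayer replicate 2) among them. INSIG1 fell too (log2 fold change -1.38, SE 0.19, adjusted p = 5.28e-05). CDKN1A fell as well (log2 fold change -0.81, SE 0.13, adjusted p = 0.000147). The gene RMRP, for the RNA of RNase MRP, which carries no poly(A) tail, rose as well (9.37, SE 0.30). Endothelial markers rose in 6 of 8 and fell in 1 (median 2.53, or 2.17 with bounds; camera adjusted p = 0.210).

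In p53-null tumours CDKN1A rose relative to monolayers (log2 fold change 1.88, SE 0.19, adjusted p = 6.91e-06). There, HMGCS1 (log2 fold change -0.98, SE 0.22, adjusted p = 0.00238) and INSIG1 (log2 fold change -1.13, SE 0.14, adjusted p = 4.26e-05) fell. Sterol synthesis genes fell in 9 of 20 and rose in 1 (9 lower over the list alone; median -0.77 relative to all genes; camera adjusted p = 0.000843, and adjusted p = 0.0646 with an estimated correlation). The list lost its call under quantile normalization (adjusted p = 0.0601). Interferon response genes rose in all 13 (median 5.93, or 4.52 with bounds; adjusted p = 0.0420 with an estimated correlation). Hypoxia genes rose in 21 of 22 (median 1.91; camera adjusted p = 4.29e-06, and adjusted p = 0.0697 with an estimated correlation). MYC and ribosome biogenesis genes fell in all 19 (median -1.58; adjusted p = 0.0420 with an estimated correlation). KRT5 rose by 9.16 (SE 0.35) and KRT6B, without a read in monolayers, was at least 190-fold higher. RMRP rose by 10.37 (SE 0.56), and the mitochondrial ATP synthase gene ATP5PO was lower (-3.60, SE 0.33).

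Of 17205 genes, 11563 (67.2%) changed in wild-type tumours, 7459 upward and 4104 downward, of which 5963 and 1820 by at least 2-fold, and quantile normalization gave 4958 and 5920. Of 17061 genes, 11515 changed in p53-null tumours, 7370 upward and 4145 downward, of which 5833 and 1962 by at least 2-fold, and quantile normalization gave 4726 and 5722. In each genotype the median over all genes lay at 0.35 on the log2 scale. Tumour libraries also differed in RNA composition. Classes that lack a poly(A) tail lay 3.25 and 4.37 above protein-coding genes in wild-type and p53-null tumours, and Spearman's rho of fold change against genomic span was 0.26 to 0.53 in each tertile of level. Genes of these classes that were scarce in monolayers passed the filter only through the tumour libraries, which partly sets the 3.25 and 4.37. The mitochondrial genome took 16.0% of reads in wild-type tumour replicate 3, which stood apart, and 8.80 to 11.2% in the other 5 tumour libraries. The 10 most abundant genes took 17.8% there and 11.2 to 12.8% in the others, and nuclear protein-coding genes 70.4% and 75.4 to 77.2%. The list changes in tumours were not separated from these.

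Simvastatin raised sterol synthesis genes in wild-type spheroids. HMGCS1 (ENSG00000112972) rose from 68.7 ± 2.89 CPM with DMSO to 557 ± 12.9 CPM (log2 fold change 3.02, SE 0.07, adjusted p = 1.06e-20). INSIG1 rose from 199.6 ± 37.8 CPM to 942 ± 13.2 CPM (log2 fold change 2.26, SE 0.09, adjusted p = 8.13e-16). Of 20 members 19 rose (median 1.84; camera adjusted p = 1.30e-40, and adjusted p = 0.0162 with an estimated correlation). So did 10 of 12 genes of sterol uptake and SREBP regulation (median 1.38; adjusted p = 0.0405 with an estimated correlation) and 8 of 9 of fatty acid synthesis (median 1.04; adjusted p = 0.0162 with an estimated correlation). FASN rose by 1.41 (SE 0.08).

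RHOB (log2 fold change 1.90, SE 0.06, adjusted p = 2.32e-17) and the transcription factor gene KLF2 (log2 fold change 1.82, SE 0.08, adjusted p = 5.79e-15) also rose in wild-type spheroids. NRF2 targets rose in 12 of 13 (median 1.04; adjusted p = 0.0494 with an estimated correlation), with the cystine transporter gene SLC7A11 (1.79, SE 0.16) and heme oxygenase, HMOX1 (1.31, SE 0.13). Integrated stress response genes rose in 11 of 18 and fell in 2 (12 and 2 over the list alone; median 0.28; adjusted p = 0.0405 with an estimated correlation), among them TRIB3 (1.13, SE 0.07). All 24 mitosis genes fell (median -0.90; adjusted p = 0.0315 with an estimated correlation), such as KIF20A (-1.35, SE 0.12). Pyrimidine synthesis genes fell in 11 of 17 and rose in 2 (median -0.40; adjusted p = 0.0405 with an estimated correlation), with TYMS (-1.004, SE 0.11), CAD (-0.75, SE 0.10) and DHODH (-0.64, SE 0.16) among those that fell. The levels of UMPS overlapped, at 36.6 to 43.4 CPM with simvastatin and 38.0 to 46.9 CPM with DMSO. The matrix genes SPP1, osteopontin (-2.65, SE 0.38), and COL12A1 (-2.07, SE 0.13) fell. CDKN1A rose by 0.55 (SE 0.07), while the p53 targets went both ways, 11 rising and 6 falling of 36 (11 and 8 over the list alone; camera adjusted p = 0.169). In all, 4177 of 14275 genes changed, 2042 upward and 2135 downward, of which 242 and 132 by at least 2-fold.

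In p53-null spheroids the same drug raised HMGCS1 from 168 ± 24.98 CPM to 434 ± 38.7 CPM (log2 fold change 1.37, SE 0.10, adjusted p = 4.11e-07). INSIG1 rose from 458 ± 31.6 CPM to 701 ± 79.2 CPM (log2 fold change 0.61, SE 0.08, adjusted p = 9.95e-05). Of 20 sterol synthesis genes 18 rose (median 0.90; camera adjusted p = 1.72e-22, and adjusted p = 0.0760 with an estimated correlation). RHOB (2.46, SE 0.09), KLF2 (2.53, SE 0.12), JUN (1.72, SE 0.09), GDF15 (1.91, SE 0.07) and CXCL8 (2.14, SE 0.15) rose as well, as did TRIM29 (2.74, SE 0.26) and the mucin gene MUC16 (2.32, SE 0.21). All 24 mitosis genes fell (median -1.21; camera adjusted p = 4.27e-25, and adjusted p = 0.0858 with an estimated correlation). Of the DNA replication genes 20 of 22 fell while 1 rose (median -0.90; camera adjusted p = 1.44e-16, and adjusted p = 0.0760 with an estimated correlation). Pyrimidine synthesis genes fell in 11 of 17 and rose in 1 (median -0.59; camera adjusted p = 3.92e-06, and adjusted p = 0.0760 with an estimated correlation), with TYMS (-1.11, SE 0.12), CAD (-0.84, SE 0.11) and DHODH (-0.81, SE 0.14) lower. UMPS moved less, at 37.7 to 42.0 CPM with simvastatin and 43.6 to 45.5 CPM with DMSO. NRF2 targets rose in 12 of 13 (median 0.98; camera adjusted p = 9.23e-15, and adjusted p = 0.0308 with an estimated correlation). The p53 targets rose in 11 and fell in 5 of 36 (14 and 6 over the list alone; median 0.17; camera adjusted p = 0.00667, and adjusted p = 0.0876 with an estimated correlation). Of 14104 genes, 3478 changed, 1618 upward and 1860 downward, of which 185 and 245 by at least 2-fold. The count was 2246 without p53-null DMSO replicate 2, and 2205 and 2146 without p53-null simvastatin replicate 1 or 2.

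Across 13786 genes the simvastatin effects of the genotypes correlated with r of 0.634 and rho of 0.646, and 75% of genes had the same sign, genes again not being independent replicates. Both genotypes shared 1114 rises and 1214 falls, against 234 and 285 for independent lists, and 8 genes were called in opposite directions.

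The rise of sterol synthesis genes with simvastatin was smaller in p53-null spheroids. The difference in response, p53-null minus wild-type, was -1.65 for HMGCS1 (SE 0.13, adjusted p = 1.72e-08), -1.65 for INSIG1 (SE 0.14, adjusted p = 3.95e-08), -1.54 for MSMO1 (SE 0.13) and -0.93 for SQLE (SE 0.11). Of 20 members 16 had a lower response (18 lower and 1 higher over the list alone; median -0.88; camera adjusted p = 3.36e-50, and adjusted p = 0.000882 with an estimated correlation). So had 7 of 12 genes of sterol uptake and SREBP regulation (9 over the list alone; median -0.70; adjusted p = 0.00624 with an estimated correlation) and 7 of 9 of fatty acid synthesis (median -0.64; adjusted p = 0.000882 with an estimated correlation). Of 36 p53 targets 2 had a higher response (median 0.05; camera adjusted p = 0.0301, and adjusted p = 0.341 with an estimated correlation). FGFBP1 also had a lower response (-2.45, SE 0.20), while GDF15 (1.11, SE 0.13), the stanniocalcin gene STC2 (0.63, SE 0.09) and the receptor kinase gene AXL (0.78, SE 0.14) had a higher one. In a comparison added after the data were seen, with simvastatin present, the sterol synthesis list was lower in p53-null than in wild-type spheroids, with a median of -0.26 and 15 of 20 members lower. In all, 107 of 14834 genes differed in response, 33 higher and 74 lower. The count was 68 and 500 without p53-null DMSO replicate 2 or 3, 62 and 64 without p53-null simvastatin replicate 1 or 2, and 63 without wild-type simvastatin replicate 2.

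**Figure D4:**
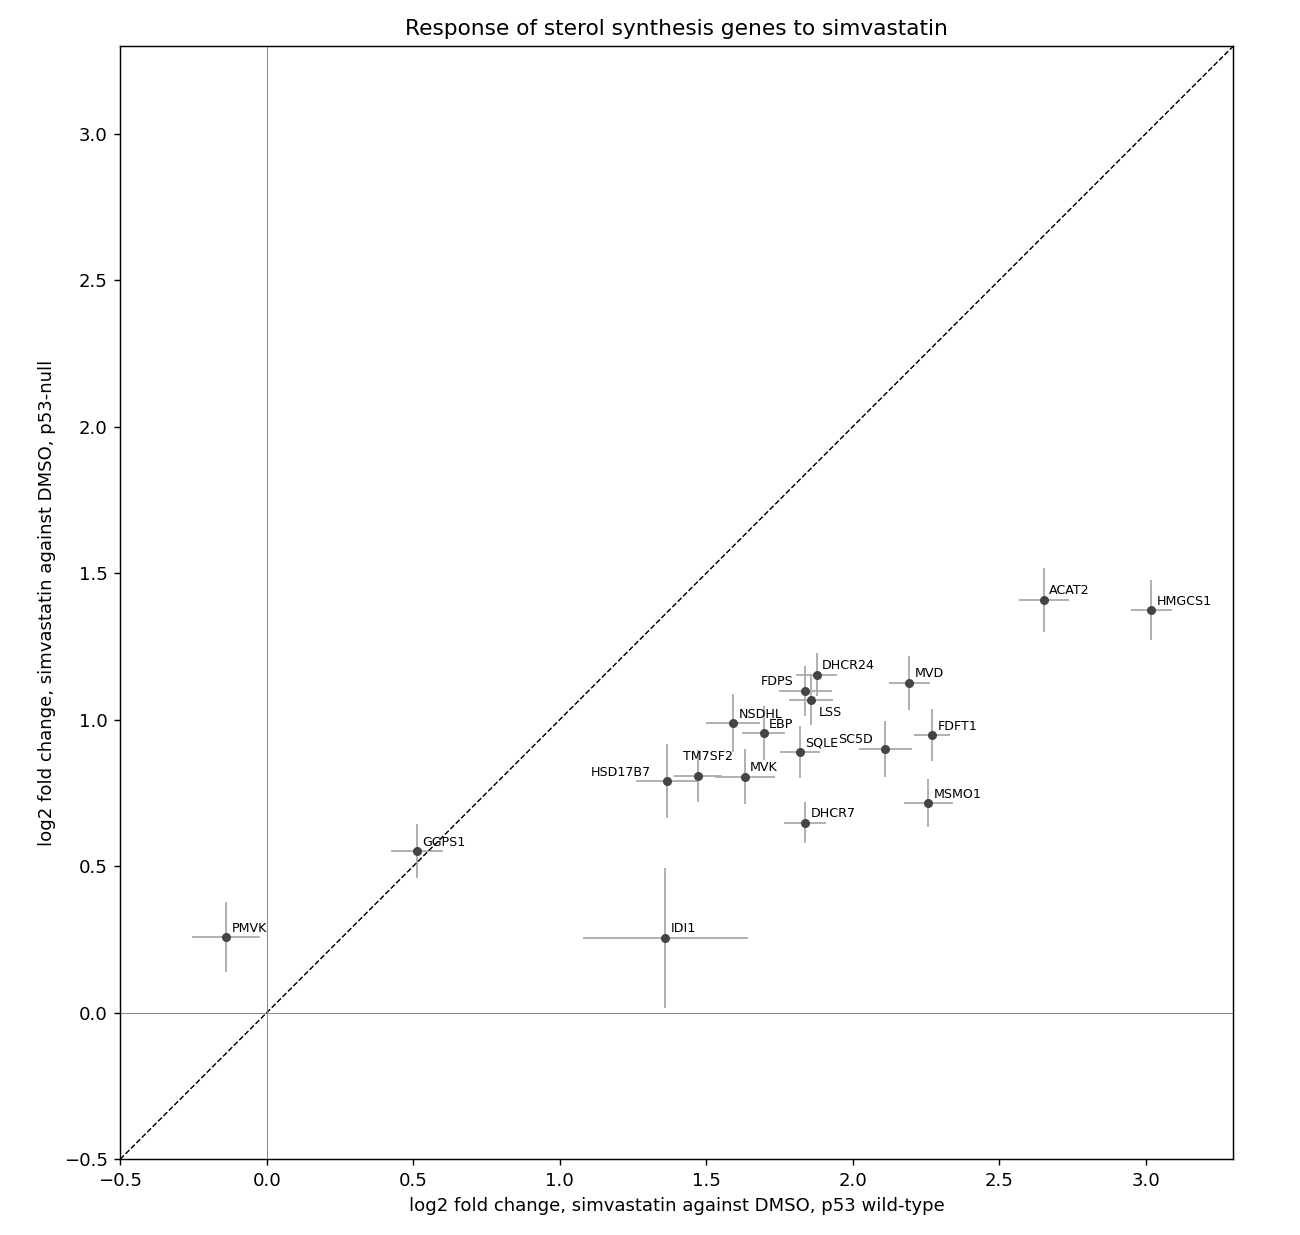
Log2 fold change with simvastatin against DMSO of 19 sterol synthesis genes in p53 wild-type (horizontal axis) and p53-null spheroids (vertical axis), with standard errors as bars and the line of equal response dashed. HMGCS1 is at 3.02 and 1.37, and 17 of the 19 genes lie below the line.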

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

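The test of sterol synthesis members that were not higher in p53-null spheroids, and the genotype comparison with simvastatin present, were chosen only after the result was seen. Each result below was singled out because a test of the difference between groups passed its threshold.

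The first set is the response to simvastatin, which differed between genotypes for 107 genes. Among the genes named whatever their result, the response in p53-null spheroids was lower for HMGCS1 (-1.65), INSIG1 (-1.65), SQLE (-0.93) and FASN (-0.68) and higher for KLF2 (0.71) and RHOB (0.56). The median differences of the lists were -0.88 for mevalonate and sterol synthesis, -0.70 for sterol uptake and SREBP regulation, and -0.64 for fatty acid synthesis. With no trend and a robust prior the calls of FASN (adjusted p = 0.198), RHOB (0.250) and KLF2 (0.354) ended, and those of RHOB (0.0507 and 0.0574) and KLF2 (0.0827 and 0.0617) also without a filter and with a median shift. RHOB lost its call without p53-null DMSO replicate 2 (adjusted p = 0.0708), p53-null simvastatin replicate 1 (0.0739) or 2 (0.0715) or wild-type simvastatin replicate 2 (0.0618). KLF2 lost it without p53-null DMSO replicate 2 (adjusted p = 0.153), p53-null simvastatin replicate 1 (0.158) or 2 (0.129), wild-type DMSO replicate 1 (0.110) or 3 (0.0813), or wild-type simvastatin replicate 1 (0.117), 2 (0.0800) or 3 (0.0584).

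The smaller rise of sterol synthesis genes in p53-null spheroids was weighed further. The scaling of the libraries was argued against, since 16 members still had a called lower response after quantile normalization. A weaker response was also argued against for the 2295 genes outside the sterol and fatty acid lists called the same way in both genotypes. Their median difference, signed by the direction of response, was 0.0446 (quartiles -0.07 and 0.17). Genes whose response weakened until it was not called in p53-null spheroids were left out of this set. Over all 13786 genes the slope of the p53-null on the wild-type effects was 0.657, which noise in the effects also lowers. A weaker response of genes outside that set is therefore left open. A higher starting level in p53-null spheroids is a candidate explanation. Across the 20 members, Spearman's rho of the difference in response against the genotype effect of the other spheroid experiment was -0.768. That experiment shares no library with this one, and genes are not independent replicates. However, the difference in response subtracts the genotype effect with DMSO, which resembled that of the other experiment. A negative rho follows wherever the genotypes lie closer with simvastatin, so it does not favour this explanation over another. A starting level is left open for members that did not start higher, of which 1, SQLE, had a called lower response, too few to decide. Because 15 of the 20 members were called lower in p53-null spheroids with simvastatin present (median -0.26), a starting level alone may not cover the whole difference. A p53-dependent response, which the design names, was not tested apart from the starting level or from other differences between the lines.

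The second set is the genotype effect in spheroids against monolayers, which differed for 131 genes. CDKN1A (2.15) and INSIG1 (0.96; adjusted p = 0.0529 with all groups of the table in the fit) had a higher genotype effect in spheroids, which for CDKN1A was a smaller drop in p53-null cells. The median differences were 0.56 for mevalonate and sterol synthesis, 0.18 for p53 targets, 0.32 for the integrated stress response, 0.55 for NF-kB and cytokines and 0.69 for histone genes. The third set is the genotype effect in tumours against monolayers, which differed for 75 genes. CDKN1A was at 2.70, its drop in p53-null monolayers not being seen in tumours.

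Other splits of the same libraries tested whether such counts arise by chance. Of 100 splits of the 12 libraries, 5 gave at least the 107 genes of the simvastatin difference (highest other 2202). At least the 131 of the spheroid difference came from 6 (highest other 2856), and at least the 75 of the tumour difference from 7 (highest other 451). Each of these numbers counts the real split as well. Each other split that reached the real count exchanged at least 2 of 3 libraries between genotypes in an environment or treatment, and a different number in the other, so that the genotype effect itself entered the difference. These splits therefore do not decide whether chance gives such counts. The 107 became 68 and 500 without p53-null DMSO replicates 2 and 3, 62 and 64 without p53-null simvastatin replicates 1 and 2, and 63 without wild-type simvastatin replicate 2. The 131 became 87 and 200 without p53-null monolayer replicates 1 and 2, 65 without wild-type monolayer replicate 2, 78 without p53-null spheroid replicate 2, and 66 and 71 without wild-type spheroid replicates 2 and 3. The 75 became 34 and 36 without p53-null monolayer replicates 1 and 3, 32, 44 and 38 without wild-type monolayer replicates 1, 2 and 3, 30 without wild-type tumour replicate 1, and 129, 38 and 31 without p53-null tumour replicates 1, 2 and 3. The splits that called several times the real number point to the genotype effect entering the difference. For each comparison of 2 groups, the 10 splits are too few for a share under 0.05: the real split alone (1 of 10) reached its count, and the highest other was 0 in limma. The real counts were 947, 1664, 417 and 2262 for genotype in monolayers, spheroids, tumours and DMSO spheroids, 7714 and 6744 for wild-type and p53-null spheroids against monolayers, 11563 and 11515 for tumours, and 4177 and 3478 for simvastatin.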

How the results depend on the processing

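The fits with voom on recovered reads and with protein-coding genes only were chosen after the result was seen. Of 187 list calls, 162 held with fry and 44 with an estimated correlation. Of the latter, 12 were for p53-null spheroids against monolayers, 10 for simvastatin in wild-type spheroids, 8 for wild-type spheroids against monolayers, 5 for the genotype difference between spheroids and monolayers, 4 for p53-null tumours against monolayers, 3 for the difference in simvastatin response, and 1 each for genotype in spheroids and simvastatin in p53-null spheroids. Quantile normalization kept 179 list calls, no filter 184 and the replicate block 184.

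Of 1232 values of named genes, direction and side of the threshold were the same for 1225 with log2(CPM + 1), 1192 with the block, 1189 with a median shift, 1178 with all groups in the fit, 1176 with no filter, 1176 with quantile normalization and 1045 with a robust prior without trend. Counts of genes moved by over 1.5 times as follows, and the cause was not tested except that the stricter filter tested fewer genes. With that filter 621 genes were called for genotype in monolayers, 270 for genotype in tumours, 6999 and 6985 for wild-type and p53-null tumours against monolayers, and 34 for the genotype difference between tumours and monolayers. A robust prior without trend gave 1067 for genotype in spheroids, 156 in tumours and 1140 in DMSO spheroids, 2450 and 1915 for simvastatin in wild-type and p53-null spheroids, and 29 for their difference. All groups in the fit gave 903 for genotype in tumours, 81 for the spheroid difference and 164 for the tumour difference. Log2(CPM + 1) gave 198 for the spheroid difference, and a median shift 122 and voom 47 for the tumour difference. Voom called 978, 1744, 433 and 2342 genes for genotype in monolayers, spheroids, tumours and DMSO spheroids, 7781 and 6760 for wild-type and p53-null spheroids against monolayers, 11819 and 11654 for tumours, 4169 and 3460 for simvastatin, and 119 and 104 for the spheroid and simvastatin differences. Without the filter, r across genes fell to 0.495 for genotype between experiments and 0.312 for simvastatin between genotypes.

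The replicate numbers did not pair the samples as a whole: no pair of groups had all correlations of same-numbered deviations over 0.1, the lowest was -0.698, and every sample correlated best with its own number only for p53-null DMSO and wild-type simvastatin spheroids (0.00407 to 0.0947). For p53-null and wild-type tumours they were 0.608, 0.216 and 0.0698, so a pairing of the tumours is left open. With the replicate number as a block, 647 genes were called for genotype in tumours and 68 for the spheroid difference, and no other count moved by over 1.5 times.

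Under quantile normalization these genes reversed and were not called: in wild-type tumours against monolayers ACTA2 (-0.96), ABCG1 (-0.93), DDIT3 (-0.36), TIE1 (-0.18), EGR3 (-0.095) and TEK (-0.058), and in p53-null tumours CKM (-0.85), BMF (-0.49), CXCL8 (-0.28), ACTA2 (-0.17) and IDI1 (-0.044). Quantile normalization gives every library 1 distribution, while tumour libraries held more genes with a read. Uncalled genes changed sign without single libraries. Genotype effects of MDM2 in monolayers ran from -0.24 to 0.26, with 0.26, 0.018 and 0.18 without p53-null replicate 2 and wild-type replicates 2 and 3. Those of HMGCS1 ran from -0.0087 (without p53-null replicate 3) to 0.32 in monolayers and from -0.39 to 0.028 (without wild-type replicate 1) in tumours, and those of CDKN1A from -0.033 (without p53-null replicate 2) to 0.31 in tumours.

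Leaving out 1 library at a time gave these ranges: 295 to 1913 genes for genotype in monolayers, 933 to 2865 in spheroids, 199 to 605 in tumours and 1278 to 2755 in DMSO spheroids. For spheroids against monolayers the ranges were 6635 to 7793 and 5087 to 6879, for tumours 10261 to 12356 and 10333 to 11046, and for simvastatin 3263 to 4207 and 2146 to 4530, in wild-type and p53-null cells. The differences ranged over 65 to 200 (spheroid), 30 to 129 (tumour) and 62 to 500 (simvastatin). List calls numbered 183 to 191, and r was 0.746 to 0.785 for genotype, 0.584 to 0.633 for simvastatin and 0.831 to 0.861 for spheroids. Tumour libraries were the shallowest, at 3611729 to 4306023 reads, and no simulated 1.5-fold genotype change was recovered there (0 of 67).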

Other observations

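With simvastatin, some genes of lysosomes and autophagy rose (log2 fold changes with SE, 3 replicates per group). In wild-type spheroids NEU1, a lysosomal sialidase gene (1.01, SE 0.08), and the autophagy receptor gene SQSTM1 (0.79, SE 0.07) rose, and in p53-null spheroids SQSTM1 (1.21, SE 0.08) and the autophagy kinase gene ULK1 (0.70, SE 0.09). The autophagy and lysosome list rose in 7 of 16 and fell in 1 in each genotype (9 and 1 over the list alone in wild-type cells). It passed camera but not with an estimated correlation, in wild-type spheroids (camera adjusted p = 0.000330, and adjusted p = 0.149 with an estimated correlation) and in p53-null spheroids (camera adjusted p = 0.000543, and adjusted p = 0.0760 with an estimated correlation). Apoptosis regulators rose in 11 of 22 and fell in 1 in wild-type spheroids (12 and 1 over the list alone; median 0.35; camera adjusted p = 7.33e-05, and adjusted p = 0.102 with an estimated correlation), among them BIRC3 (1.00, SE 0.08) and BBC3 (0.67, SE 0.08).

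In camera, genes of endoplasmic reticulum protein folding went in opposite directions in wild-type spheroids and tumours. In wild-type cells the unfolded protein response list rose in 9 of 16 and fell in 4 in spheroids against monolayers (10 and 4 over the list alone; camera adjusted p = 0.00216, and adjusted p = 0.0708 with an estimated correlation), with the chaperone gene HSPA5 at 1.11, SE 0.08 and DNAJB9 at 2.48, SE 0.12. In wild-type tumours against monolayers it rose in 1 and fell in 11 (camera adjusted p = 4.92e-05, and adjusted p = 0.113 with an estimated correlation), with HYOU1 at -1.40, SE 0.13 and PDIA6 at -1.30, SE 0.12. The serine synthesis gene PHGDH was lower in both, at -2.29, SE 0.10 in spheroids and -2.15, SE 0.15 in tumours, as was asparagine synthetase, ASNS, at -1.28, SE 0.09 and -2.78, SE 0.13. The difference between the spheroid and tumour effects was not tested.

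Of the tests below, those of mouse host cells and of S phase were chosen only after the result was seen. Tumour libraries held more RNA of small structural and ribosomal classes than monolayer libraries. With RMRP and RN7SK with its copies left out because they had been seen, the classes that lack a poly(A) tail lay 3.25 above protein-coding genes on the log2 scale in wild-type tumours (17 genes, quartiles 3.06 and 5.92) and 4.37 in p53-null tumours (18 genes), each gene being higher. A gene under 1 CPM in every monolayer library entered only through the tumour libraries, so this direction was partly set by the filter. A larger share of RNA without a poly(A) tail in these libraries stays a candidate explanation. The test cannot decide it, because these classes are also the pattern to be explained. Longer genes also rose more: Spearman's rho of fold change against genomic span, in the later build, was 0.26 or higher at low, middle and high expression level in both genotypes, across genes, which is in line with more unspliced RNA. Mouse host cells are left open. Of 28 fibroblast and leukocyte markers, 8 stood at 1 CPM or more in tumours of either genotype and above every monolayer library of that genotype, among them the leukocyte genes ITGAM, CSF1R, ITGB2 and LYZ, named after their values were seen, and 2 (COL1A1 and SPARC) at 8 CPM or more. Those 2 also had reads in wild-type and p53-null monolayers, at 20.1 and 15.9 CPM for COL1A1 and 7.45 and 1.05 CPM for SPARC, so they need not mark host cells. The markers CD68, TYROBP, C1QA, C1QB, S100A8, S100A9, LUM, THY1 and PDGFRA stood at 0 CPM in tumours of both genotypes. A first bound on this test was set aside because mouse RNA need not align to the human genome. Tumour growth itself stays open and untested, and the list changes in tumours were not separated from this composition.

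Histone genes were higher in spheroids than in monolayers, in 7 of 8 tested genes in wild-type and 7 of 9 in p53-null cells. More cells in S phase is argued against, since the DNA replication list fell, with medians of -1.40 in wild-type and -1.49 in p53-null cells on the deposited scale (-1.25 and -1.23 relative to the median of all genes). More RNA without a poly(A) tail cannot be told apart from a change in the cells: these classes lay 0.94 above protein-coding genes in p53-null spheroids (6 genes) and 0.49 in wild-type spheroids (3 genes), too few and too variable to decide. A change of histone transcripts with growth in spheroids may therefore contribute and was not tested.

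Reads assigned to a pair of genes, chosen after their values were seen, followed the tumours as well. Those assigned to HFM1 stood at 16499 to 25279 CPM in tumours and 80.5 to 610 CPM in the cultured libraries of the first experiment. Those assigned to MALAT1 stood at 4165 to 7070 and 336 to 2109 CPM. In the second experiment HFM1 reached 2903 CPM in wild-type simvastatin replicate 2. Whether the reads assigned to HFM1 came from transcripts of that gene was not tested, so its values do not show a change of the gene itself.

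Of the 26 genes named whatever their result, 16 were higher, 4 lower and 6 not called with simvastatin in wild-type spheroids, and 13, 3 and 10 in p53-null spheroids. For genotype these numbers were 0, 5 and 20 in monolayers (25 tested), 8, 5 and 13 in spheroids, 2, 2 and 22 in tumours, and 5, 8 and 13 in DMSO spheroids. They were 11, 7 and 8 for wild-type and 13, 6 and 7 for p53-null spheroids against monolayers, and 6, 9 and 11 and 7, 7 and 12 for tumours. Differences were called for 2 higher in spheroids, 1 higher in tumours, and 2 higher and 6 lower with simvastatin.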
